A study of Mus musculus with 46 samples.

How the data were processed

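RNA of 46 mouse samples in 23 groups of 2 was compared after loss of Arid1a, a DNA-binding subunit of the SWI/SNF chromatin remodelling complex, or after treatments of such cells. Per the labels, the samples were B16F10 melanoma tumors and cultures, MC38 colon carcinoma cells and mouse embryonic fibroblasts (MEFs). The double-knockout labels name the cell line B16F11 to B16F14, which was taken as B16F10. Libraries were made from polyA RNA, except 4 total RNA libraries used for repeats. Per the submitters' processing notes, reads were aligned to GRCm38/mm10 with STAR 2.5.3a and counted with HOMER. The file headers give the HOMER commands and state no strand option, so reads of overlapping antisense transcripts may be counted with a gene, and values of close paralogs are uncertain.

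The table of the BD98 experiment holds raw exon counts, per the file headers. The other 8 tables hold normalized log2 values deposited by the authors, with low values drawn together in the manner of a regularized logarithm. The authors' fold changes and p-values stand beside the values in the deposited tables and were used only for counts of their calls and for single values named as theirs. The design had assumed counts or unlogged values; the tests were changed to those the log2 values need, with no pseudocount. Values from different tables were normalized separately and were compared only as fold changes. Each gene table has 24537 genes, and 5433 to 7940 of them were 0 in all libraries of a table. For 10 columns of the tables that belong to no comparison here, the values were not used.

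Groups, comparisons, gene lists and a first set of alternatives were fixed before the data were examined. On log2 values, limma 3.58.1 (limma-trend) was used on genes with a mean log2 value of at least 4. On counts, edgeR 4.0.16 was used with TMM size factors, filterByExpr and the quasi-likelihood test, and DESeq2 1.42.0 as an alternative. All groups of a table were fitted together, in R 4.3.3. P-values were adjusted with the Benjamini-Hochberg method, and a gene was called at an adjusted p under 0.05. Errors given after ± are standard errors of the log2 fold change. The 28 gene lists covered interferon responses, antigen presentation, nucleic acid sensing, chromatin, pigmentation, matrix, replication, stress and metabolism, and cell types. Lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, and also with an estimated correlation and with fry, which tests whether the genes of a list move one way. With an estimated correlation, camera takes its degrees of freedom from the libraries of the fit, so it has little power with few libraries. These were fewest in tumors, MC38 cells and MEFs, where the lack of such a call does not count against a list. The fry values are in the result tables only. A count described as adjusted over the list alone comes from Benjamini-Hochberg adjustment over the members of that list. The p-values measure only the spread between samples, which may be technical.

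Genes were named by a rule: the targeted genes, a panel of interferon-response genes, up to 5 genes with the largest rise and 5 with the largest fall at a mean log2 value of at least 3 with no overlap between groups, and up to 4 members of a list with the smallest p. Some genes that the rule picked are not reported. In the double-knockout table, the share of each gene's 31-mers found in transcripts of another gene was computed from GENCODE vM21. For repeats, the log2 values of loci with a mean of at least 2 were averaged per subfamily with at least 5 such loci, out of 5147736 loci in the table, of which 1804944 were not all 0. A set of genes higher with the sgArid1a label in other experiments was followed through each treatment.

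The scripts were tested on simulated data built on the libraries of 10 gene comparisons, with 200 changed genes each. For repeats, 800 subfamilies were simulated with 1 fixed spread not taken from the repeat libraries, and 200 of them were changed. At a planted log2 fold change of 1, limma recovered 94.0% in tumors, 100% in the PBS cultures, 100% for the interaction, 95.5% in untreated cultures, 95.5% for anti-IFNAR, 95.5% in the DMSO cultures, 100% in MC38 cells and 97.0% in MEFs. At 0.5 it recovered 49.2%, 97.0%, 94.0%, 49.2%, 69.7%, 66.7%, 98.5% and 74.2% in the same order. For limma the folds were planted on the scale of the deposited log2 values, which draw low values together. Recovery of folds in the RNA before that step was not measured. For BD98, edgeR recovered 85.1% at 1 and 66.7% at 0.5, and DESeq2 77.6% and 58.2%. For anti-IFNAR after BD98 these were 84.8% and 68.3%, and 77.6% and 58.2%. For the simulated repeats the recovery was 100% at 1 and 76.1% at 0.5, which does not measure recovery in the repeat libraries. False calls numbered 0 to 16 per simulation, and of 100 random lists of 40 genes in each of 8 comparisons none was called. Genes were simulated independently of each other, so these lists cannot test the preset correlation.

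Alternatives were no filter, a replicate block, each library left out in turn, only the libraries compared in the fit, DESeq2 and RLE size factors for counts, and repeats per locus. Centring of libraries on their median, quantile normalization, restriction to genes with little shared sequence, the followed set taken without the IFNγ experiment, loci summed per subfamily, and the count of DMSO knockout genes in the double-knockout libraries were added after the values had been seen. Replicate pairs were checked for identity, and the SD of their difference ranged from 0.037 to 0.246 in the log2 tables. Tables were read with pandas 2.3.3 and numpy 2.4.6, and figures were drawn with matplotlib 3.10.9.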

Results

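RNA was sequenced from mouse cells and tumors with and without Arid1a, the DNA-binding subunit of the SWI/SNF chromatin remodelling complex. The 46 libraries formed 23 groups of 2. B16F10 melanoma cells carried a control guide (sgScramble) or a guide against Arid1a (sgArid1a). They were taken as tumors on day 15, as cultures given PBS or interferon-gamma (IFNγ) for 24 h, as untreated cultures, or as cultures given an antibody against the type I interferon receptor (anti-IFNAR), DMSO or ruxolitinib, an inhibitor of JAK1 and JAK2, for 72 h. Untreated cultures labelled as sgArid1a with an additional knockout of Cgas or Sting1 were set against the untreated cultures. The labels do not say whether they were sequenced in the same run. A compound with the code name BD98 was given to sgScramble cells for 72 h, alone or with anti-IFNAR. MC38 colon carcinoma cells carried the same kinds of guide, and Arid1a-floxed MEFs were given ethanol or tamoxifen and taken on day 5. Depth per library was 31.6 to 38.8 M reads in tumors, 27.2 to 31.2 in the IFNγ experiment, 8.7 to 22.8 in the untreated, double-knockout and anti-IFNAR cultures, and 14.4 to 20.3 in the ruxolitinib experiment. It was 16.1 to 30.3 M reads with BD98, 13 to 13.9 in MC38, 11 to 21.9 in MEFs and 62.6 to 73.0 in total RNA.

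The targeted gene was read first in each library. Arid1a (NM_001080819) lies on the minus strand of mm10 chromosome 4 from 133679008 to 133753611. In tumors its log2 value was 11.71 and 11.57 with sgScramble and 11.24 and 11.41 with sgArid1a. In untreated cultures it was 10.90 and 11.08 with sgScramble and 10.43 and 10.39 with sgArid1a. In the table of the anti-IFNAR experiment, which holds the same untreated libraries, it was 10.95 and 11.10 with sgScramble, 10.57 and 10.53 with sgArid1a, and 10.60 and 10.61 with anti-IFNAR. With DMSO it was 11.76 and 11.29 in sgScramble and 11.29 and 11.24 in sgArid1a, and with ruxolitinib 11.08 and 11.17. MC38 cells had 10.69 and 10.71 with sgScramble and 10.59 and 10.53 with sgArid1a, and MEFs had 10.52 and 10.79 with ethanol and 10.12 and 10.32 with tamoxifen. In the BD98 experiment Arid1a was at 8.03 and 8.12 log2 (CPM + 1) with DMSO, 7.67 and 7.77 with BD98, and 7.86 and 7.88 with BD98 and anti-IFNAR. A guide that shifts the reading frame can leave much of the transcript in place, so these values check the labels only in part.

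In the IFNγ experiment Arid1a did not follow the guide labels. Libraries labelled sgScramble had 12.42 and 12.40 with PBS and 12 and 12.11 with IFNγ. Libraries labelled sgArid1a had 12.25 and 12.40 with PBS and 12.15 and 12.13 with IFNγ. In the libraries labelled Cgas double knockout Arid1a was at 11.03 and 10.74, near the sgScramble values, and in those labelled Sting1 double knockout at 10.71 and 10.83. Cgas, listed as Mb21d1 (mm10 chromosome 9, 78430518 to 78443237, minus strand), was at 8.03 and 7.98 in the libraries labelled Cgas double knockout and at 8.06 and 7.96 in sgArid1a cells. Sting1, listed as Tmem173 (chromosome 18, 35733678 to 35740554, minus strand), was at 9.04 and 8.87 in the libraries labelled Sting1 double knockout and at 9.47 and 9.51 in sgArid1a cells.

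**Figure D1:**
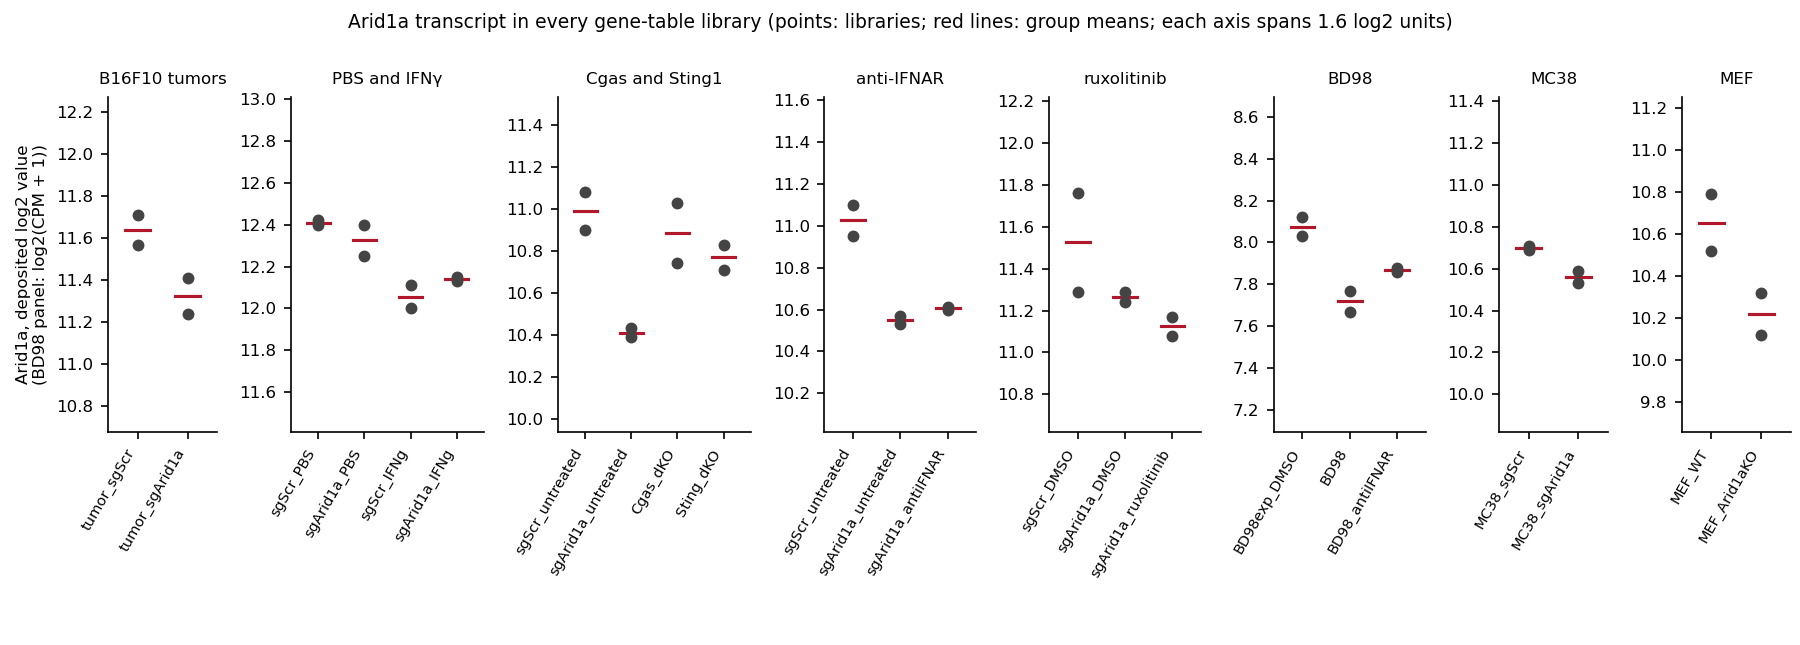
Arid1a in every library of the gene tables, by group, as deposited log2 values, or as log2 (CPM + 1) for BD98. Points are libraries and lines are group means, and each axis spans the same range.

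The first comparison asked what Arid1a loss changed in melanoma tumors. Arid1a fell by 0.32 ± 0.07 (log2, n = 2 tumors per group, adjusted p = 0.0031). The antiviral genes that type I interferon induces rose: Isg20, an exonuclease that degrades viral RNA, by 1.93 ± 0.07 (adjusted p = 8.9e-10), Rsad2 by 1.49 ± 0.07, Ifit3 by 1.42 ± 0.08 (adjusted p = 2.5e-08) and Isg15 by 1.22 ± 0.07 (adjusted p = 3.4e-08). Of the 51 tested type I interferon-stimulated genes, 50 rose and 0 fell, with a median of 0.87 (camera adjusted p = 9.1e-24, adjusted p = 0.086 with an estimated correlation). Of 26 IFNγ-leaning genes 25 rose and 1 fell (adjusted p = 6.8e-17, adjusted p = 0.086 with an estimated correlation). Among them were the T cell attractant Cxcl9, up 2.43 ± 0.07 (adjusted p = 1.6e-10), the GTPase Igtp, up 2.38, and H2-Aa of MHC class II, up 1.86. MHC class I presentation rose in 19 of 21 genes, such as H2-K1 by 1.91 ± 0.06 and the immunoproteasome subunit Psmb8 by 2.04 ± 0.07 (list adjusted p = 2.0e-13, adjusted p = 0.15 with an estimated correlation).

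Cytosolic nucleic acid sensors moved both ways in tumors: 15 of 25 rose and 5 fell (adjusted p = 0.0024, adjusted p = 0.15 with an estimated correlation). The RNA sensor Ddx58 rose by 1.02, while Mb21d1, the DNA sensor upstream of Sting1, fell by 0.65 ± 0.07 (adjusted p = 1.3e-05). Of 9 interferon ligand, receptor and JAK-STAT genes 3 rose, among them Ifngr1 by 0.38, and the list was not called. Chemokines were not called as a list: 7 of 15 rose and 4 fell. Cxcl16 rose by 1.59, Ccl8 by 1.41, Ccl5 by 0.71 and Cxcl10 by 0.20 ± 0.07 (adjusted p = 0.022), and the neutrophil attractant Cxcl5 fell by 0.88.

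Proliferation genes fell in tumors. Markers of other cells changed there too, as given below. Falls of proliferation or pigment genes are therefore not separated from a change in cell mix. The same holds for the rises in tumors, such as those of interferon, antigen presentation, chemokine and stress response genes. Of 27 cell cycle genes 26 fell and 0 rose, among them the replicative helicase subunit Mcm2 at -0.78 ± 0.06 and the clamp Pcna at -0.75, with a list median of -0.55 (adjusted p = 1.1e-11, adjusted p = 0.086 with an estimated correlation). Of 28 R-loop and replication stress factors 18 fell and 0 rose, such as Brca1 at -1.20 ± 0.06 and Rpa1 at -0.64 (adjusted p = 0.00038, adjusted p = 0.33 with an estimated correlation). Of 20 p53 target genes 12 rose and 2 fell, with the cell cycle inhibitor Cdkn1a up 1.07 ± 0.07 and Btg2 up 1.06, while Perp fell by 1.32 (list adjusted p = 0.0021, adjusted p = 0.15 with an estimated correlation). Unfolded protein and integrated stress response genes rose, 15 of 17, such as the chaperone Dnajb9 by 1.63 ± 0.07 (adjusted p = 3.7e-09) and the transcription factor Ddit3 by 1.22 ± 0.06. That list had a median of 0.80 (adjusted p = 1.5e-09, adjusted p = 0.086 with an estimated correlation).

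Pigment cell genes fell in tumors, 11 of 18 with 3 rising: the receptor Kit fell by 1.78 ± 0.06, the melanocortin receptor Mc1r fell by 1.42 and the melanosome transporter Oca2 fell by 1.14 (list adjusted p = 0.00073, adjusted p = 0.19 with an estimated correlation). Cholesterol biosynthesis fell in 14 of 21 genes and rose in 1, with a list median of -0.36 (adjusted p = 0.00063, adjusted p = 0.15 with an estimated correlation). Hypoxia and glycolysis genes fell in 10 of 16 and rose in 2, with Ndrg1 at -0.39 and P4ha1 up 0.47 (adjusted p = 0.034, adjusted p = 0.46 with an estimated correlation). The mesenchymal, NF-kB and SWI/SNF lists were not called. Of 28 mesenchymal genes 6 rose and 12 fell, with Axl up 0.97. Of 18 NF-kB targets 9 rose and 5 fell, with Vcam1 up 1.76 and Ptgs2 at -1.22. Of 25 SWI/SNF subunits 4 rose and 11 fell, with Smarcd3 up 0.70 and Actl6a at -0.50.

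Markers of other cells changed in the tumors, each a mixture of cells. All 10 tested muscle genes rose, with a median of 2.55, among them the myosin Myh1 by 2.91 ± 0.07 (adjusted p = 4.0e-11), the creatine kinase Ckm by 2.60 and the actin Acta1 by 3.16 ± 0.09 (list adjusted p = 1.4e-12, adjusted p = 0.086 with an estimated correlation). Macrophage markers rose in 15 of 17, with a median of 0.86, such as the complement gene C1qa by 1.26 ± 0.06 (adjusted p = 9.4e-09) and Cx3cr1 by 1.41 (list adjusted p = 1.9e-10, adjusted p = 0.086 with an estimated correlation). T cell markers rose in 6 of 7, with Cd4 up 0.70 and Cd8a up 0.38 (adjusted p = 0.0049, adjusted p = 0.29 with an estimated correlation). Cytotoxic and NK markers rose in 5 of 6, with Klrk1 up 0.49 and Gzmb up 0.43 (adjusted p = 0.010, adjusted p = 0.19 with an estimated correlation). Dendritic cell markers rose in 7 of 9, with Wdfy4 up 0.85 and Ccr7 up 0.74 (adjusted p = 0.00073, adjusted p = 0.15 with an estimated correlation). Endothelial markers rose in 10 of 12 and fell in 2, with Kdr up 0.52 (adjusted p = 0.0056, adjusted p = 0.34 with an estimated correlation). All 5 adipocyte markers rose, Cfd by 1.23 (adjusted p = 0.00059, adjusted p = 0.19 with an estimated correlation). Fibroblast markers split, 5 up and 5 down of 11, with Fbln1 at -1.10 and Pdgfrb up 0.34. Lists with under 5 tested members had no list test: 4 of 4 erythroid genes fell, with Hbb-bs at -1.68 ± 0.07, 3 of 4 neutrophil genes fell and 1 rose, 2 of 3 B cell genes rose and 1 fell, and 1 of 1 keratinocyte gene rose.

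**Figure D2:**
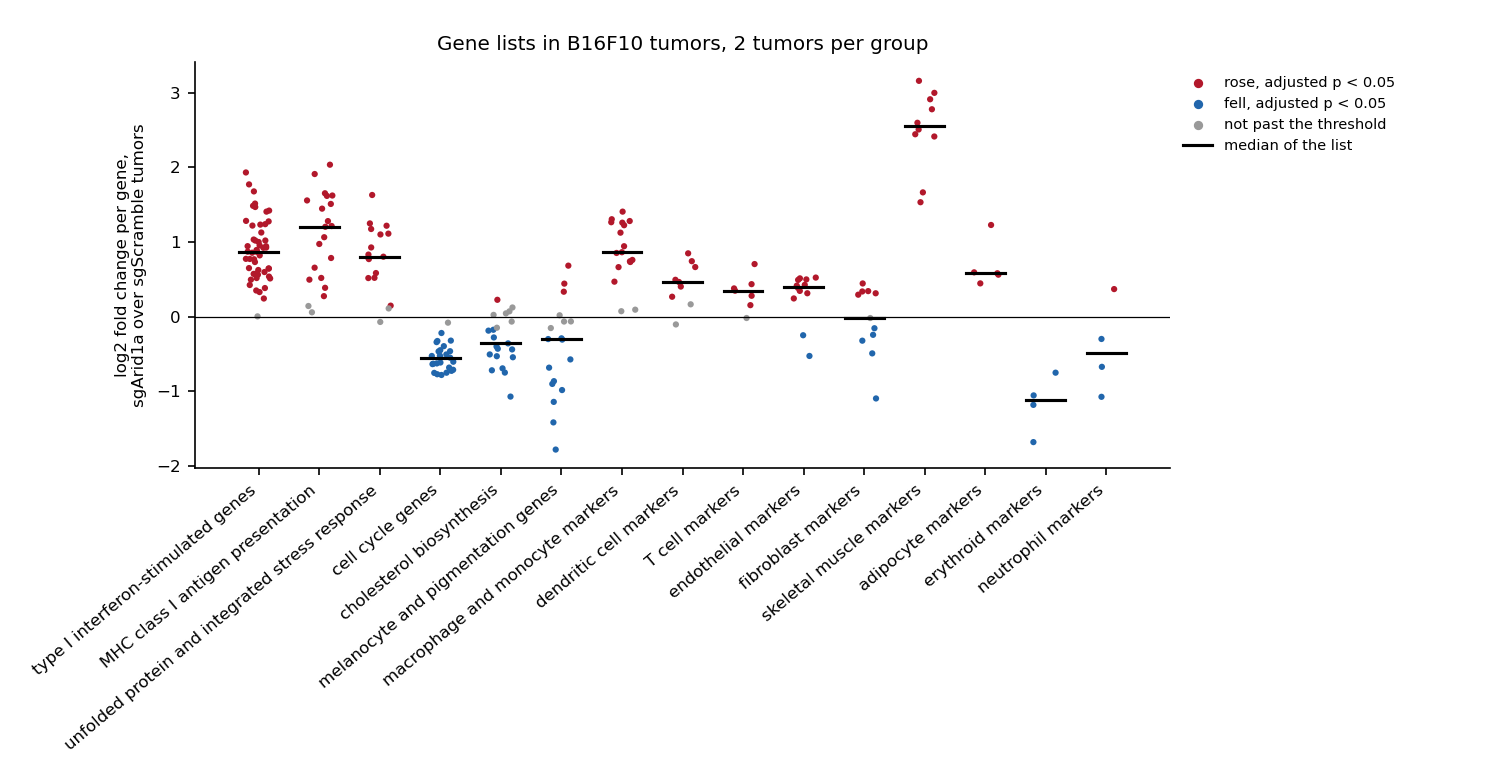
Log2 fold change of each member of gene lists in sgArid1a over sgScramble tumors, 2 tumors per group. Points are genes colored by call and black lines are list medians.

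Among single genes, the largest rises in tumors were of the muscle gene Igfn1 by 4.85 ± 0.08 (adjusted p = 3.8e-12), the cartilage collagens Col2a1 by 4.28 and Col11a2 by 3.74, and the stress hormone Fgf21 by 4.12. The largest falls were those of C1ql3 at -2.44 ± 0.09 (adjusted p = 6.6e-10), Crmp1 at -2.37, Sytl2, a melanosome transport protein, at -2.32, and Serpinb2 at -2.28. Of 13895 tested genes, limma called 3611 higher and 3898 lower, and 295 and 88 of these by a log2 of at least 1.

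The same loss was asked about in untreated cultures, with no other cells present. Arid1a fell by 0.58 ± 0.11 (n = 2 per group, adjusted p = 0.0043). Ifit1, which binds foreign RNA caps, rose by 1.04 ± 0.12 (adjusted p = 0.00011), Ifit3 by 0.98 ± 0.15, Parp14 by 0.96, Rsad2 by 0.92 and Isg15 by 0.59 ± 0.10 (adjusted p = 0.0028). The same libraries as normalized in the table of the anti-IFNAR experiment gave smaller rises, Ifit1 by 0.69 ± 0.08, Rsad2 by 0.68, Ifit3 by 0.62, Parp14 by 0.61 and Isg15 by 0.34 ± 0.06 (adjusted p = 0.0076), with 28 of 41 type I interferon-stimulated genes rising and a median of 0.34 (adjusted p = 0.025 with an estimated correlation). In the untreated table, of 41 type I interferon-stimulated genes 31 rose and 0 fell, with a median of 0.54 (adjusted p = 1.0e-20, adjusted p = 0.0066 with an estimated correlation), and 35 rose when adjusted over the list alone. IFNγ-leaning genes rose in 6 of 8, such as Irgm1 by 0.99, and in 8 adjusted over the list alone. MHC class I genes rose in 10 of 18, Psmb8 by 0.72, and in 12 adjusted over the list alone (adjusted p = 6.8e-07, adjusted p = 0.063 with an estimated correlation). Of 19 sensors 7 rose, Ddx58 by 0.66 (adjusted p = 4.5e-05, adjusted p = 0.034 with an estimated correlation).

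Sterol genes rose in untreated cultures: 17 of 20 cholesterol genes, and 20 adjusted over the list alone, among them Mvd by 1.13 and Hmgcs1 by 0.69 (list median 0.59, adjusted p = 1.5e-18, adjusted p = 0.028 with an estimated correlation). Of 17 unfolded protein and integrated stress response genes 12 fell and 4 rose, with a median of -0.86 (adjusted p = 1.1e-08, adjusted p = 0.036 with an estimated correlation). Those that fell included Trib3 at -2.77 ± 0.15 (adjusted p = 1.8e-07), Ddit3 at -2.32 ± 0.12 (adjusted p = 9.3e-08), Chac1 at -2.30 and Atf3 at -1.98. The endoplasmic reticulum chaperone Hspa5 rose by 1.19 ± 0.10. The amino acid and one-carbon gene Aldh1l2 fell by 2.23. Cell cycle genes rose in 8 of 27, and in 14 adjusted over the list alone, such as Bub1b by 0.48 (list median 0.26, adjusted p = 1.5e-07, adjusted p = 0.028 with an estimated correlation). Pigment genes fell in 8 of 17, Trpm1 at -2.27 ± 0.10 (adjusted p = 2.5e-08), Kit at -1.42 and Oca2 at -0.93 (adjusted p = 1.6e-07, adjusted p = 0.094 with an estimated correlation). Hypoxia genes fell in 6 of 16 and rose in 1, with Vegfa at -0.92 (adjusted p = 8.3e-06, adjusted p = 0.18 with an estimated correlation), and 4 of 5 fibroblast markers fell, Fbln1 at -1.08 (adjusted p = 0.00013, adjusted p = 0.038 with an estimated correlation). The chemokines Cxcl10, at 0.30 (adjusted p = 0.17), and Ccl5, at -0.09 (adjusted p = 0.52), did not pass.

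Of 11604 genes in untreated cultures, limma called 678 higher and 694 lower, 1372 in all. With a replicate block it called fewer, 678 in all. The count was 508 without sgArid1a replicate 1, 451 without sgArid1a replicate 2, 2840 without sgScramble replicate 2, and 642 with only these libraries in the fit.

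Cells with DMSO were an independent pair of groups for the same question. Arid1a was at -0.26 ± 0.12 (n = 2 per group, adjusted p = 0.23), which did not pass. Trim30a rose by 0.59 ± 0.08 (adjusted p = 0.0010), Parp14 by 0.58, Ddx58 by 0.52, Usp18, which removes Isg15 from proteins, by 0.48 and Ifit1 by 0.42 (adjusted p = 0.022). Isg15 was at 0.18 ± 0.07 (adjusted p = 0.11). Of 42 type I interferon-stimulated genes 24 rose and 0 fell, with a median of 0.30 (adjusted p = 1.7e-17, adjusted p = 0.031 with an estimated correlation), and 33 rose adjusted over the list alone. MHC class I genes rose in 6 of 19, and in 12 adjusted over the list alone (adjusted p = 1.6e-06, adjusted p = 0.13 with an estimated correlation). Cholesterol genes rose in 15 of 21 and fell in 1, Hmgcs1 by 0.61 (list median 0.34, adjusted p = 1.8e-12, adjusted p = 0.034 with an estimated correlation). Of 17 stress response genes 12 fell and 4 rose, with a median of -0.69, Trib3 at -2.35 ± 0.09 (adjusted p = 1.7e-08), Chac1 at -1.70 and Ddit3 at -1.36 (list adjusted p = 1.1e-09, adjusted p = 0.17 with an estimated correlation). The stress-induced regulator Nupr1 fell by 2.49 ± 0.08 (adjusted p = 3.2e-09). Trpm1 fell by 1.52 ± 0.10 (adjusted p = 1.7e-06) and Kit fell by 0.70, and 5 of 17 pigment genes fell (adjusted p = 0.00029, adjusted p = 0.25 with an estimated correlation). Cell cycle genes rose in 4 of 27, and in 9 adjusted over the list alone (list median 0.16, adjusted p = 0.00086, adjusted p = 0.097 with an estimated correlation). The potassium channel Kcnj13 rose by 1.40 ± 0.13 and Cited1 by 0.85.

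With DMSO, limma called 412 of 11783 genes higher and 516 lower, 928 in all. The count was 182 without sgArid1a replicate 1, 197 without sgArid1a replicate 2, 3240 without sgScramble replicate 1 and 1704 without sgScramble replicate 2. Across 11431 genes, fold changes in DMSO and untreated cultures correlated with r = 0.715, where genes are not independent replicates. Both comparisons raised 253 genes against 23.9 expected, and lowered 331 against 29.6 expected.

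Whether Cgas and Sting1, the DNA sensor and its adaptor that induce type I interferon, were needed for the rise was asked with the libraries labelled double knockout. Each was set against the same untreated sgArid1a libraries. No sgScramble cells with a knockout of either gene were sequenced, so loss of the rise is not separated from a fall independent of Arid1a loss. Arid1a was higher than in sgArid1a cells by 0.47 ± 0.11 (n = 2 per group, adjusted p = 0.0060) in the libraries labelled Cgas double knockout and by 0.36 ± 0.11 (adjusted p = 0.024) in those labelled Sting1 double knockout, so Arid1a does not bear out these labels. Against sgScramble, of 406 genes that the knockout raised in the DMSO cultures 279 were higher and 19 lower with the Cgas label, and 297 higher and 16 lower with the Sting1 label. Of 491 that it lowered there, 371 were lower and 7 higher with the Cgas label, and 392 lower and 5 higher with the Sting1 label. Ddit3 was at -2.01 and -2.16 and Kit at -1.65 and -1.80, but Trpm1 was at 0.17 (adjusted p = 0.18) and -0.66, Oca2 at 0.02 (adjusted p = 0.92) and -0.39, and Tyr at 0.43 and 0.48. Mb21d1 was at 0.00 ± 0.11 (adjusted p = 0.99) in the libraries labelled Cgas double knockout, and Tmem173 fell by 0.54 ± 0.10 (adjusted p = 0.0015) in those labelled Sting1 double knockout. In the libraries labelled Cgas double knockout, Oas1g, which senses double-stranded RNA, fell by 1.53, Ifit1 fell by 1.35 ± 0.12 (adjusted p = 1.5e-06), Ifit3 fell by 1.24 ± 0.15 (adjusted p = 3.8e-05), Isg15 fell by 0.85 ± 0.10 (adjusted p = 4.1e-05) and Cxcl10 fell by 0.84. Of 41 type I interferon-stimulated genes 28 fell and 0 rose, with a median of -0.42 (adjusted p = 1.2e-09, adjusted p = 0.030 with an estimated correlation), and 30 fell adjusted over the list alone. In the libraries labelled Sting1 double knockout, Oas1g fell by 1.49, Ifit1 fell by 1.39 ± 0.12 (adjusted p = 1.1e-06), Ifit3 fell by 0.89 ± 0.15 and Isg15 fell by 0.83 ± 0.10 (adjusted p = 5.0e-05). There 24 of 41 fell and 1 rose, with a median of -0.34 (adjusted p = 1.1e-06, adjusted p = 0.065 with an estimated correlation). Against sgScramble the list was not called with either label: 8 rose and 7 fell with the Cgas label, and 12 rose and 6 fell with the Sting1 label.

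Other lists also moved in the double-knockout libraries. MHC class I genes fell in 10 of 18 with the Cgas label, H2-K1 at -2.19 ± 0.13 (adjusted p = 7.5e-06, adjusted p = 0.19 with an estimated correlation), and in 12 of 18 with the Sting1 label, H2-K1 at -1.92 (adjusted p = 0.00013, adjusted p = 0.27 with an estimated correlation). Hypoxia and glycolysis genes fell in 12 of 16 with the Cgas label, Pgk1 at -2.89 (adjusted p = 1.2e-09, adjusted p = 0.19 with an estimated correlation), and in 13 with the Sting1 label, Pgk1 at -3.59 (adjusted p = 1.1e-09, adjusted p = 0.27 with an estimated correlation). Trpm1 rose by 2.43 ± 0.10 (adjusted p = 5.3e-10) and Tyr, the key enzyme of melanin synthesis, by 1.06 with the Cgas label, and Trpm1 by 1.61 with the Sting1 label. The largest falls were those of Gm5148 at -6.60 and C330021F23Rik at -6.22 with the Cgas label, and at -6.45 and -6.10 with the Sting1 label. Among housekeeping genes, Actg1 fell by 5.54 ± 0.13 (adjusted p = 4.1e-12) and Gapdh fell by 5.52 ± 0.19 with the Cgas label, and Actg1 fell by 5.95 ± 0.13 with the Sting1 label. Of Gapdh 31-mers 84.1% occur in other genes' transcripts, of Actg1 57.1%, of Pgk1 68.3%, of Ifit3 61.8%, of H2-K1 23.4%, of Isg15 13.1% and of Arid1a 2.62%. Of 706 genes with over 50% shared 31-mers, 31.9% fell below -1 with the Cgas label and 33.1% with the Sting1 label, and 0 did between the untreated guides. Of 7494 genes with at most 5% shared, 0.347% and 0.440% did. Among interferon-stimulated genes with at most 5% shared, 12 of 19 fell and 0 rose with the Cgas label, with a median of -0.37 (adjusted p = 7.7e-07, adjusted p = 0.067 with an estimated correlation), and 9 of 19 fell and 1 rose with the Sting1 label, with a median of -0.26 (adjusted p = 0.00012, adjusted p = 0.14 with an estimated correlation). MHC class I was not called among genes with at most 5% shared: 1 of 5 fell with the Cgas label (median -0.11, adjusted p = 0.34) and 1 of 5 with the Sting1 label (median 0.06, adjusted p = 0.63). Of hypoxia and glycolysis genes with at most 5% shared, 6 of 8 fell with the Cgas label (median -0.75, adjusted p = 2.5e-08, adjusted p = 0.21 with an estimated correlation) and 7 of 8 with the Sting1 label (median -0.70, adjusted p = 4.4e-08, adjusted p = 0.29 with an estimated correlation).

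**Figure D3:**
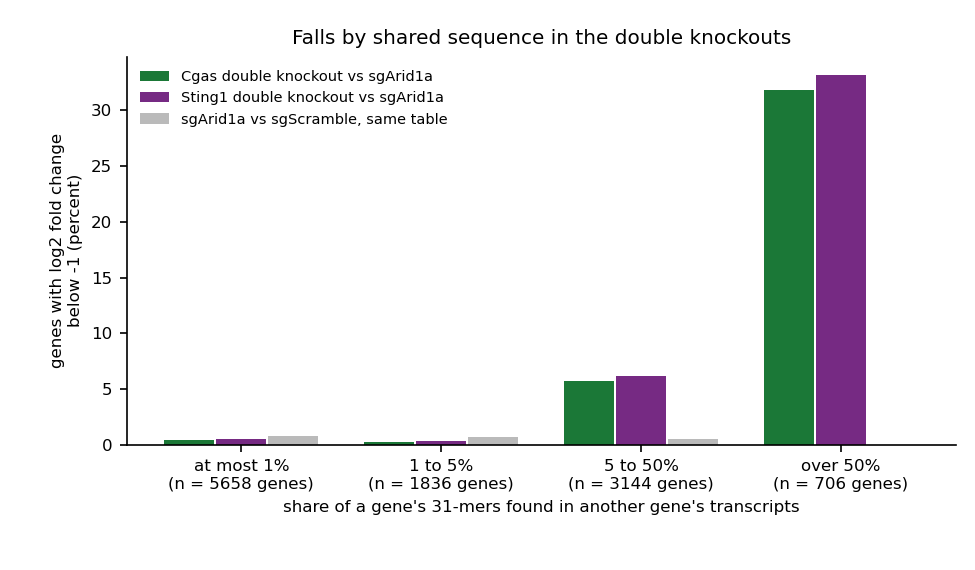
Percent of genes with a log2 fold change below -1, by the share of a gene's 31-mers found in transcripts of other genes. Bars show the double-knockout libraries by label and the untreated guides.

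With the Cgas label, limma called 1416 genes higher and 1913 lower, 3329 in all, against 2338 and 1525 after quantile normalization. The count was 1468 without Cgas double knockout replicate 1, 2124 without replicate 2, 2130 without sgArid1a replicate 1, 1592 without sgArid1a replicate 2, and 5135 with only these libraries in the fit. It was 1067 higher and 670 lower, 1737 in all, among genes with at most 5% shared 31-mers. With the Sting1 label, 1611 were higher and 2077 lower, 3688 in all, against 2145 and 1767 after centring on the median and 2566 and 1598 after quantile normalization. The count was 1610 without Sting1 double knockout library b, 2101 without sgArid1a replicate 1, 1893 without sgArid1a replicate 2, and 2078 (1261 higher, 817 lower) among genes with at most 5% shared 31-mers. In the libraries with the Sting1 label against those with the Cgas label, limma called 1 gene higher and 3 lower, with 900 at an unadjusted p under 0.05.

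Anti-IFNAR was used to ask whether the rise in sgArid1a cells ran through the type I interferon receptor. No sgScramble cells were given it alone, and the labels name no control antibody. Loss of the rise is thus not separated from a fall independent of Arid1a loss. Arid1a was at 0.06 against sgArid1a cells without it (adjusted p = 1). Ifi27, an interferon-induced mitochondrial protein, fell by 0.94 ± 0.08 (n = 2 per group, adjusted p = 0.0046) and Irf9, the DNA-binding part of the complex downstream of that receptor, fell by 0.60 ± 0.07 (adjusted p = 0.023). Rtp4, at -0.41 ± 0.06 (adjusted p = 0.065), and Oas1g, at -0.42 (adjusted p = 0.14), did not pass. As a list, the 41 type I interferon-stimulated genes were lower, with a median of -0.23 (camera adjusted p = 1.5e-64, adjusted p = 0.0044 with an estimated correlation), and 26 fell adjusted over the list alone. The IFNγ-leaning list was lower too, with 4 of 8 falling adjusted over the list alone (adjusted p = 3.1e-12, adjusted p = 0.053 with an estimated correlation). Against sgScramble, 8 interferon-stimulated genes stayed higher and 1 was lower. Of 11686 genes limma called 0 higher and 2 lower, with 150 at an unadjusted p under 0.05, and the authors' deposited table calls 0 higher and 34 lower. The count was 18 with only these libraries in the fit, 1 without anti-IFNAR replicate 1, 0 without anti-IFNAR replicate 2, 0 without sgArid1a replicate 1 and 0 without sgArid1a replicate 2.

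Ruxolitinib was used to ask whether the rise needed JAK kinases, which act below interferon receptors. No sgScramble cells were given it, so loss of the rise is not separated from a fall independent of Arid1a loss. Arid1a was at -0.14 ± 0.12 (adjusted p = 0.68). Rtp4 fell by 0.80 ± 0.06 (n = 2 per group, adjusted p = 6.4e-05), Irf9 fell by 0.74, Usp18 fell by 0.70, Ifit3 fell by 0.67 ± 0.07 (adjusted p = 0.00079), Ddx58 fell by 0.64 and Isg15 fell by 0.47 (adjusted p = 0.0082). Of 42 type I interferon-stimulated genes 16 fell and 0 rose, with a median of -0.28 (adjusted p = 9.0e-40, adjusted p = 0.0091 with an estimated correlation), and 33 fell adjusted over the list alone. Of 8 IFNγ-leaning genes 3 fell, and 6 adjusted over the list alone (adjusted p = 5.9e-09, adjusted p = 0.11 with an estimated correlation). MHC class I genes had a median of -0.18, with 0 of 19 called and 11 falling adjusted over the list alone (adjusted p = 3.9e-08, adjusted p = 0.13 with an estimated correlation). Against sgScramble with DMSO, 8 interferon-stimulated genes were lower and 0 higher, and that list was not called (adjusted p = 0.078). In all, limma called 3 genes higher and 23 lower, with 1169 at an unadjusted p under 0.05, where the authors' deposited table calls 133 higher and 455 lower. The count of 26 became 89 with only these libraries in the fit, 17 without ruxolitinib replicate 2, 7 without sgArid1a DMSO replicate 1 and 4 without sgArid1a DMSO replicate 2.

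The BD98 experiment asked what the compound did in sgScramble melanoma cells. Arid1a fell by 0.48 ± 0.07 (n = 2 per group, adjusted p = 2.1e-06). Interferon-stimulated genes rose, Ifit3 by 3.67 ± 0.16 (adjusted p = 1.4e-16), Ifit1 by 3.46 ± 0.12 (adjusted p = 4.0e-18), the interferon-inducing factor Irf7 by 3.23 and Isg15 by 3.08 ± 0.13 (adjusted p = 8.8e-17). Of 44 such genes 43 rose and 1 fell, with a median of 2.20 (adjusted p = 3.3e-52, adjusted p = 0.079 with an estimated correlation). IFNγ-leaning genes rose in 11 of 12 and fell in 1, Igtp rising by 3.77 (adjusted p = 1.8e-11, adjusted p = 0.079 with an estimated correlation), and MHC class I genes in 17 of 19, Psmb8 by 4.19 ± 0.27 and the peptide transporter Tap2 by 2.44 (adjusted p = 1.7e-14, adjusted p = 0.057 with an estimated correlation). Of 18 sensors 13 rose and 2 fell: Dhx58 rose by 3.23, Ddx58 by 2.42, Tmem173 by 0.51 ± 0.08 (adjusted p = 1.5e-05) and Mb21d1 by 0.46 ± 0.12 (adjusted p = 0.0021) (list adjusted p = 5.1e-05, adjusted p = 0.083 with an estimated correlation).

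Pigment genes all fell with BD98, 17 of 17, among them the melanin enzymes Dct at -2.01 ± 0.08 (adjusted p = 1.3e-17) and Tyrp1 at -1.88 ± 0.07, Trpm1 at -2.32 ± 0.10 and the melanosome transport gene Rab27a at -1.64 (list median -1.40, adjusted p = 6.8e-36, adjusted p = 0.062 with an estimated correlation). Of 25 SWI/SNF subunits 16 fell and 2 rose, with Arid1b at -0.72 and Smarcd1 at -0.64 and the neuronal subunit Dpf1 up 1.57, and the list was not called (adjusted p = 0.063). Cell cycle genes fell in 18 of 27 and rose in 2, Mcm2 at -0.77 (adjusted p = 0.0056, adjusted p = 0.33 with an estimated correlation), and the repair gene Brca1 fell by 1.09. Cholesterol genes rose in 13 of 21 and fell in 2 (adjusted p = 0.0088, adjusted p = 0.26 with an estimated correlation). Of 17 stress response genes 11 fell, with Ddit3 at -1.83 and Trib3 at -1.13, and 4 rose, with Xbp1 up 1.15 and Hspa5 up 0.99, and the list was not called (adjusted p = 0.096). Matrix genes split: Postn fell by 2.42 and Fbln1 fell by 2.08, while Cyr61 rose by 1.93 and Fn1 by 1.72. The differentiation inhibitor Id3 rose by 4.20 ± 0.14. Of 12843 genes edgeR called 3148 higher and 3259 lower, and DESeq2 2617 and 2753.

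Adding anti-IFNAR to BD98 asked which of these changes ran through the type I interferon receptor. No cells were given anti-IFNAR without BD98 in this experiment, so its effect on interferon genes without BD98 is not separated. Rtp4 fell by 3.72 ± 0.17 (n = 2 per group, adjusted p = 4.6e-14) against BD98 alone, Irf7 fell by 2.23, Dhx58 fell by 2.10, Isg15 fell by 1.92 ± 0.11 (adjusted p = 6.3e-12), Ifit3 fell by 1.89 and Ifit1 fell by 1.51. Of 44 type I interferon-stimulated genes 42 fell and 0 rose, with a median of -1.44 (adjusted p = 8.9e-303, adjusted p = 0.013 with an estimated correlation), and 43 fell adjusted over the list alone. IFNγ-leaning genes fell in 8 of 12, Igtp at -1.64 (adjusted p = 9.3e-38, adjusted p = 0.020 with an estimated correlation), and MHC class I genes in 10 of 19, or 17 adjusted over the list alone (adjusted p = 1.1e-24, adjusted p = 0.013 with an estimated correlation). The proliferation marker Mki67 rose by 0.29 (adjusted p = 0.022) and Cdkn1a fell by 0.37. Against DMSO, 29 of 44 interferon-stimulated genes stayed higher and 6 were lower, with a median of 0.70 (adjusted p = 1.5e-06, adjusted p = 0.34 with an estimated correlation). No pigment gene was called between BD98 with and without anti-IFNAR, and 17 of 17 stayed lower than with DMSO, Dct at -2.02. Arid1a was at 0.14 (adjusted p = 0.43) between them. For this step edgeR called 14 genes higher and 178 lower, 192 in all, and DESeq2 10 and 135. A replicate block raised the edgeR count, as given below. The count was 343 without the filter, 86 without BD98 with anti-IFNAR replicate 2, 321 without BD98 replicate 1 and 810 without BD98 replicate 2.

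In MC38 colon carcinoma cells the question was whether Arid1a loss acts outside melanoma. Arid1a fell by 0.14 ± 0.03 (n = 2 per group, adjusted p = 0.00087). Ifi27 rose by 0.95 ± 0.03 (adjusted p = 1.4e-19), Lgals3bp by 0.81, Oasl2 by 0.80 ± 0.04, the RNA helicase Helz2 by 0.79, Isg15 by 0.67 ± 0.03 (adjusted p = 1.1e-16) and Usp18 by 0.61. Of 48 type I interferon-stimulated genes 47 rose and 0 fell, with a median of 0.35 (adjusted p = 2.1e-71, adjusted p = 0.16 with an estimated correlation). IFNγ-leaning genes rose in 11 of 13 (adjusted p = 3.8e-14, adjusted p = 0.16 with an estimated correlation). MHC class I genes rose in 10 of 19, Tap1 by 0.44, and fell in 2, the folding factors Calr at -0.23 and Pdia3 at -0.22 (adjusted p = 2.8e-05, adjusted p = 0.25 with an estimated correlation). Several inflammatory and matrix genes fell: the monocyte attractant Ccl2 fell by 0.62, Vcam1 fell by 0.54, Fn1 fell by 0.43 and Axl fell by 0.40. Of 14 NF-kB targets 5 fell and 1 rose (adjusted p = 0.00066, adjusted p = 0.16 with an estimated correlation), and of 20 mesenchymal genes 9 fell and 4 rose (adjusted p = 0.00066, adjusted p = 0.16 with an estimated correlation). Cell cycle genes fell in 12 of 27 and rose in 1, Pcna at -0.26 (list median -0.08, adjusted p = 7.3e-05, adjusted p = 0.16 with an estimated correlation). Stress response genes fell in 10 of 16, Hspa5 at -0.28 (list median -0.09, adjusted p = 8.0e-05, adjusted p = 0.23 with an estimated correlation), and cholesterol genes in 7 of 21 (list median -0.06, adjusted p = 0.0021, adjusted p = 0.60 with an estimated correlation). The largest rises included the inositol transporter Slc5a3 by 0.88 and Cotl1 by 0.82, and the largest falls the protease Htra1 at -0.83 and the collagen Col7a1 at -0.74. Of 11516 genes limma called 959 higher and 1484 lower, 2443 in all, against 1334 and 1214 after centring on the median. The count was 1482 without the filter, 1160 without sgArid1a replicate 1 and 1156 without sgArid1a replicate 2, and the authors' deposited table calls 283 higher and 631 lower.

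MEFs tested the same loss in cells that are not tumor cells. Arid1a fell by 0.43 ± 0.09 (n = 2 per group, adjusted p = 0.012) with tamoxifen. Isg15 rose by 2.04 ± 0.06 (adjusted p = 2.4e-08), Usp18 by 1.97, Lgals3bp by 1.97, Ifit1 by 1.88 and the virus tether Bst2 by 1.76. Cxcl10 rose by 1.29 and Ccl5 by 0.50, and 4 of 10 chemokines rose (adjusted p = 7.4e-05, adjusted p = 0.13 with an estimated correlation). Of 43 type I interferon-stimulated genes 42 rose and 0 fell, with a median of 0.93 (adjusted p = 9.5e-79, adjusted p = 0.11 with an estimated correlation). IFNγ-leaning genes rose in 13 of 14, Igtp by 0.98 (adjusted p = 5.9e-20, adjusted p = 0.13 with an estimated correlation), and MHC class I genes in 17 of 19, Tapbp by 0.96 and Tap1 by 0.67 (adjusted p = 7.3e-18, adjusted p = 0.11 with an estimated correlation). Of 22 sensors 11 rose, Ddx58 by 1.52, Ifih1 by 1.16 and Mb21d1 by 0.25 ± 0.05 (adjusted p = 0.014) (list adjusted p = 1.7e-09, adjusted p = 0.13 with an estimated correlation). Of 19 p53 targets 8 rose, Cdkn1a by 0.74 ± 0.06 (adjusted p = 3.9e-05) and Btg2 by 0.47 (list adjusted p = 2.2e-07, adjusted p = 0.11 with an estimated correlation). Cholesterol genes fell in 12 of 21, and in 18 adjusted over the list alone, Hmgcs1 at -0.50 and Insig1 at -0.43 (list median -0.25, adjusted p = 4.4e-12, adjusted p = 0.11 with an estimated correlation). Glycolysis and hypoxia genes fell in 9 of 15, Ldha at -0.49 and Eno1 at -0.44 (adjusted p = 4.9e-08, adjusted p = 0.11 with an estimated correlation). Fibroblast markers rose in 3 of 8, Col3a1 by 0.74 (list median 0.06, adjusted p = 0.016, adjusted p = 0.47 with an estimated correlation). The largest falls included Cd24a at -0.99 ± 0.07, the lactate exporter Slc16a3 at -0.92 and the integrin Itga5 at -0.65. Of 12184 genes limma called 572 higher and 611 lower, against 646 and 440 after centring on the median. Deviations of same-numbered MEF libraries correlated at 0.686, though the labels name no shared batch. With a replicate block the count was much higher, as given below. Tamoxifen was given to one side only, so its own effect is not separated from that of Arid1a loss.

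Some folds were smaller here than in the authors' deposited tables. The log2 values used here draw low values together, which can make folds smaller, but the cause was not tested. Own and deposited folds correlated at 1 with BD98, whose table holds counts, and at 0.652 in MC38 cells. Sizes of folds and list medians are not comparable between experiments. In MEFs Irf7 rose by 1.19 here and by 4.14 in the authors' deposited table. In MC38 cells Ifit1 rose by 0.42 here and by 1.65 in the authors' deposited table.

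Interferon-stimulated genes were compared across the 5 Arid1a comparisons outside the IFNγ experiment, which share no library. Of the list, 22 genes rose in all 5, among them Ifit1, Ifit3, Rsad2, Cmpk2, Irf9, Usp18, Parp14, Rtp4 and Ddx58, and 31 rose in at least 4. Of the 50 that rose in tumors, 32 also rose in untreated or DMSO cultures.

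**Figure D4:**
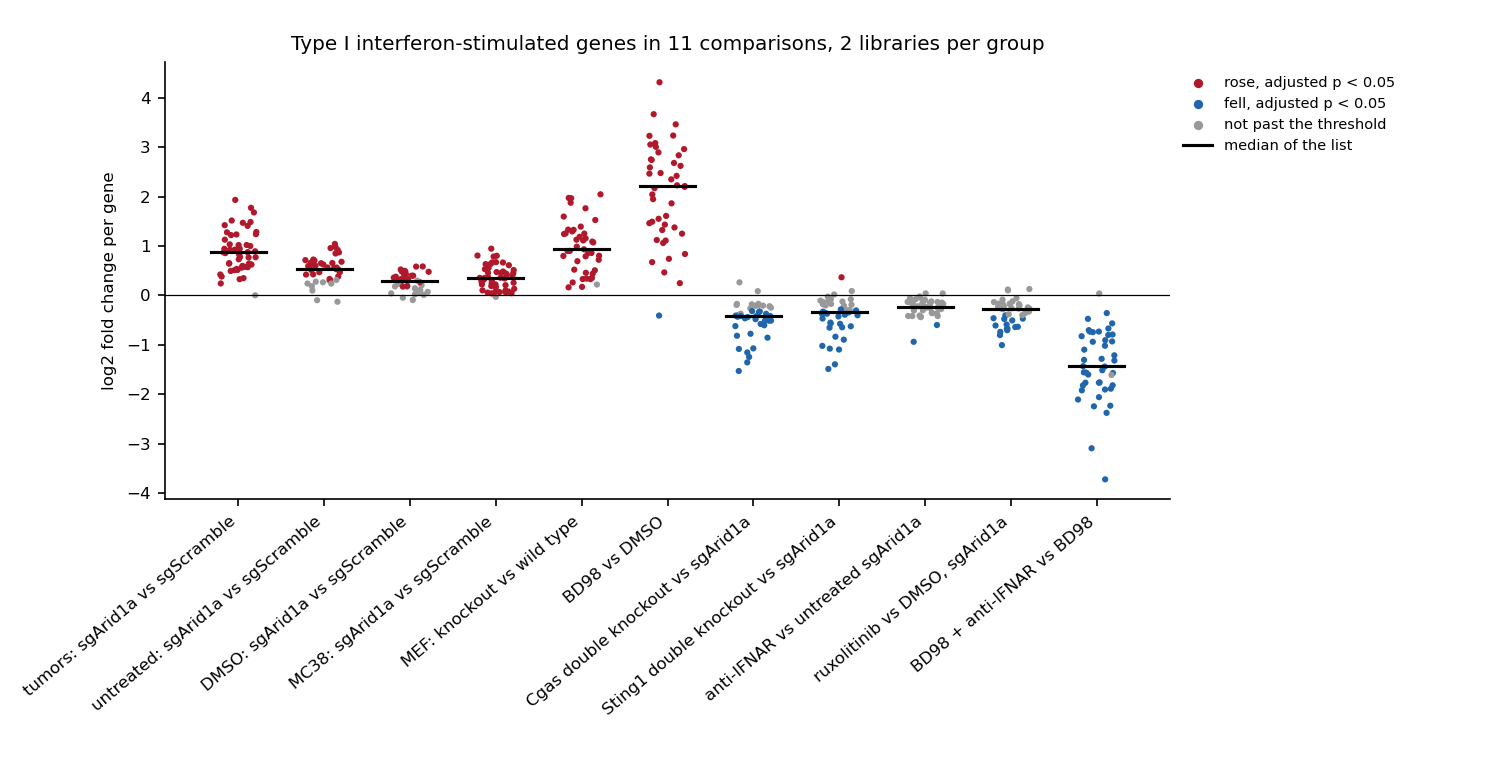
Log2 fold change of type I interferon-stimulated genes in 11 comparisons, 2 libraries per group. Sizes of folds are not comparable between experiments. Points are genes colored by call and black lines are list medians.

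The IFNγ experiment asked how Arid1a loss changes the response to IFNγ. Here Arid1a was at -0.08 ± 0.05 (n = 2 per group, adjusted p = 0.51) between the libraries labelled sgArid1a and sgScramble in PBS and at 0.09 ± 0.05 (adjusted p = 0.35) in IFNγ, and it fell by 0.35 ± 0.05 (adjusted p = 1.7e-05) from the libraries labelled sgScramble PBS to those labelled sgScramble IFNγ. All directions in this experiment follow the deposited labels, which Arid1a does not bear out. Between the libraries labelled PBS, the IFNγ-induced GTPases Irgm2 and Igtp were higher with the sgArid1a label by 4.57 ± 0.05 (adjusted p = 3.9e-19) and 4.57 ± 0.09, Gbp2 by 3.65 and the MHC class I activator Nlrc5 by 2.95. Of 45 type I interferon-stimulated genes 42 were higher and 0 lower, 44 adjusted over the list alone, with a median of 0.67 (adjusted p = 6.4e-117, adjusted p = 0.013 with an estimated correlation). Of 22 IFNγ-leaning genes 21 were higher (adjusted p = 1.3e-85, adjusted p = 0.026 with an estimated correlation), of 19 MHC class I genes 17 (adjusted p = 9.3e-89, adjusted p = 0.014 with an estimated correlation), and of 21 sensors 9. Of 12357 genes limma called 293 higher and 43 lower, 336 in all, and 252 and 80 after centring on the median. The count was 208 without the library labelled sgArid1a PBS 1, 214 without sgScramble PBS 1 and 214 without sgScramble PBS 2.

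Between the libraries labelled sgScramble IFNγ and sgScramble PBS, the IFNγ-leaning list was not called (6 of 22 higher, adjusted p = 0.12), and Irgm2 rose by 0.23 ± 0.05. Interferon-stimulated genes were higher in 14 of 45 and lower in 1, with Ifitm3 at -1.02 ± 0.05 (list median 0.08, adjusted p = 0.0019, adjusted p = 0.68 with an estimated correlation). Pigment genes were lower, Trpm1 at -2.21 ± 0.04 (adjusted p = 1.1e-16), Oca2 at -1.86 and Tyr at -1.07, 9 of 17 with 2 higher (adjusted p = 0.0018, adjusted p = 0.16 with an estimated correlation). Of 18 p53 targets 16 were lower (adjusted p = 1.4e-12, adjusted p = 0.13 with an estimated correlation), and of 21 cholesterol genes 19 (adjusted p = 1.6e-10, adjusted p = 0.37 with an estimated correlation). Id3 was higher by 3.04 ± 0.10 (adjusted p = 9.4e-13), Fgfr3 by 2.43 and Col11a2 by 2.13, and the matrix protein Spp1 was lower by 2.18. In this contrast 1943 genes were higher and 2383 lower.

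Between the libraries labelled sgArid1a IFNγ and sgArid1a PBS, 43 of 45 interferon-stimulated genes were higher and 1 lower, with a median of 0.56 (adjusted p = 1.2e-22, adjusted p = 0.17 with an estimated correlation). H2-Ab1 of MHC class II was higher by 1.27, Psmb8 by 1.11 and Isg15 by 0.63. Trpm1 was lower by 2.25 ± 0.04 (adjusted p = 8.5e-17), Spp1 fell by 2.24 and Oca2 fell by 1.78, and Id3 was higher by 2.88 ± 0.10, near the values under the sgScramble label. All 18 of 18 p53 targets and 20 of 21 cholesterol genes were lower. In this contrast 2585 genes were higher and 2636 lower, and Arid1a was lower by 0.18 ± 0.05 (adjusted p = 0.0051).

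Between the libraries labelled IFNγ, 45 of 45 interferon-stimulated genes were higher with the sgArid1a label, with a median of 1.12 (adjusted p = 2.4e-122, adjusted p = 0.012 with an estimated correlation), and so were 22 of 22 IFNγ-leaning genes, Igtp by 5.41 ± 0.09 (adjusted p = 3.6e-17) and Irgm2 by 5.02 ± 0.05. P53 targets were lower in 12 of 18, Cdkn1a at -0.38 (list adjusted p = 2.4e-13, adjusted p = 0.026 with an estimated correlation). The NF-kB subunit Relb was lower by 0.43, as were 3 of 9 NF-kB targets. In this contrast 498 genes were higher and 334 lower, 832 in all, against 453 and 579 after centring on the median and 442 and 459 after quantile normalization. The count was 495 without the library labelled sgArid1a IFNγ 1, 488 without sgArid1a IFNγ 2 and 1597 without sgScramble IFNγ 2.

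The interaction tested whether the labelled IFNγ response differed between the labelled guides. H2-Ab1 was higher by 1.27 ± 0.09 (adjusted p = 1.3e-06), Psmb8 by 1.05 ± 0.11 (adjusted p = 6.6e-05), Ifit3 by 0.93 ± 0.09 (adjusted p = 2.8e-05) and Rtp4 by 0.92, and the adhesion molecule Mcam was lower by 0.48, Trib3 fell by 0.44 and Cdkn1a fell by 0.38. Of 45 interferon-stimulated genes 26 were higher and 0 lower, 40 adjusted over the list alone, with a median of 0.36 (adjusted p = 2.0e-58, adjusted p = 0.045 with an estimated correlation). Of 22 IFNγ-leaning genes 18 were higher (adjusted p = 4.5e-44, adjusted p = 0.066 with an estimated correlation). In all 86 genes were higher and 23 lower, 109 together. The count was 56 without the filter, 59 without the library labelled sgArid1a IFNγ 1, 60 without sgArid1a PBS 2, 881 without sgScramble IFNγ 2, 57 without sgScramble PBS 1 and 71 without sgScramble PBS 2.

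**Figure D5:**
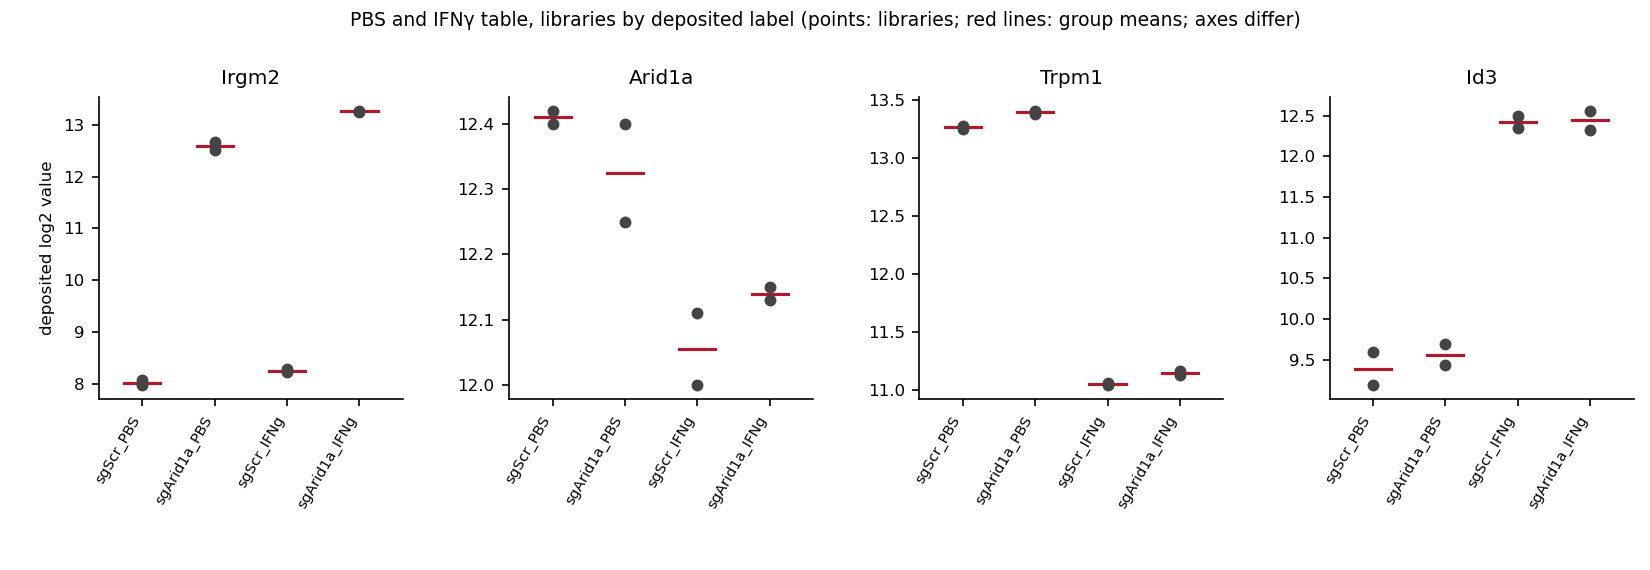
Deposited log2 values of single genes in the PBS and IFNγ libraries, by deposited label. Points are libraries and lines are group means, with a separate axis per gene.

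A set of genes higher with the sgArid1a label in other experiments was followed to ask whether the treatments returned it. It was drawn from other experiments because the untreated sgArid1a libraries enter both the untreated comparison and the ones that test a return. For the double-knockout labels and anti-IFNAR the set held the 51 genes higher both between the libraries labelled PBS and in DMSO cultures. For ruxolitinib it held the 76 higher both between the libraries labelled PBS and in untreated cultures. Of these, 15 and 29 lay outside the interferon lists. Each of these genes rests on the IFNγ experiment, whose labels Arid1a does not bear out. For BD98 another set was used, of 292 genes higher in at least 2 of 3 comparisons: between the libraries labelled PBS, in untreated cultures and in DMSO cultures. Not each of these rests on the IFNγ experiment. In the libraries labelled Cgas double knockout, 31 of 50 set genes fell, with a median of -0.41, and in those labelled Sting1 double knockout 25 fell, with a median of -0.32. With anti-IFNAR 2 of 50 fell and 45 were lower, with a median of -0.17. With ruxolitinib 18 of 76 fell, with a median of -0.22. Against sgScramble the set had a median of 0.27 in the libraries labelled Cgas double knockout (20 of 50 higher, 3 lower), 0.29 in those labelled Sting1 double knockout (25 higher, 2 lower) and 0.16 with anti-IFNAR (21 higher, 1 lower). With ruxolitinib it was 0.10, with 10 of 76 higher and 7 lower (p = 0.019, p = 0.053 with an estimated correlation). BD98 raised 141 of 289 set genes and lowered 63, with a median of 0.23, and anti-IFNAR on top lowered 48 of 289, with a median of -0.0058. The set taken without the IFNγ experiment gave medians of 0.07 with the Cgas label (81 of 406 rose, 79 fell), 0.08 with the Sting1 label (103 rose, 68 fell) and 0.02 with anti-IFNAR (0 of 405 rose, 2 fell). For the Sting1 label camera called it higher (p = 0.012, p = 0.048 with an estimated correlation). With ruxolitinib the median was -0.04, where 18 of 672 fell and 0 rose, and camera called the set lower (p = 0.00014, p = 0.11 with an estimated correlation). With anti-IFNAR after BD98 it was 0.0086, but 35 of 251 fell and 0 rose, and camera called the set lower (p = 9.2e-09, p = 0.031 with an estimated correlation). Against sgScramble, that set had medians of 0.44 with the Cgas label (279 of 406 higher, 19 lower), 0.47 with the Sting1 label (297 higher, 16 lower), 0.28 with anti-IFNAR (241 of 405 higher, 2 lower) and 0.20 with ruxolitinib (225 of 672 higher, 8 lower).

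Total RNA asked whether repeats, a possible source of nucleic acid ligands, changed with Arid1a loss in B16F10 cells. The endogenous retrovirus IAPEz-int was at 0.20 ± 0.08 (n = 2 per group, adjusted p = 0.57), over 2413 loci. The LINE subfamily L1Md_A was at -0.12, ETnERV-int at 0.06, MERVL-int at -0.03 and the major satellite GSAT_MM at -0.97 ± 0.69. The smallest p belonged to the retroviral LTR RLTR9B, at 0.26 ± 0.03 (adjusted p = 0.34). By class, LTR elements were at 0.04 (adjusted p = 0.45), and LINE and SINE elements both at 0.01. Of 840 subfamilies limma called 0, with 71 at an unadjusted p under 0.05, 502 with a fold above 0 and 338 below. With loci summed per subfamily it called 3 higher and 3 lower, and of 21220 loci tested singly 209 higher and 362 lower. Among the 103654 loci kept here, the authors' deposited table calls 25 higher and 100 lower.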

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

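The test between the labelled guides was planned, and the search for opposite lists and all tests of explanations were chosen after the results had been seen. The response labelled as one to IFNγ differed between the labelled guides in 109 genes, with a median of 0.36 for the type I interferon list, and was picked out as a difference between groups. Lists called in opposite directions in different Arid1a comparisons were also picked out, at the preset correlation. A first version of that search also asked for a call with an estimated correlation and found none. That test has little power with the few libraries of tumors, MC38 cells and MEFs, so the first version could hardly find a list there. Cell cycle genes had medians of -0.55 in tumors and -0.0777 in MC38 cells but 0.26 in untreated and 0.16 in DMSO cultures. Cholesterol genes were at -0.36 in tumors, -0.0622 in MC38 cells and -0.25 in MEFs, but at 0.59 in untreated and 0.34 in DMSO cultures. Stress response genes were at 0.80 in tumors but at -0.86 in untreated cultures, -0.69 in DMSO cultures and -0.0925 in MC38 cells. Fibroblast markers were at -0.53 in untreated and -0.35 in DMSO cultures and at 0.0598 in MEFs. These tables were normalized separately and the differences between them were not tested. The medians in tumors are also not separated from a change in cell mix.

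In the IFNγ experiment the labels may not match the libraries, a question that the Arid1a values raised and so do not test. A treatment that did not reach the sgScramble cells would leave few differences between the groups with that label, but 4326 genes differed. Arid1a loss alone, with no added IFNγ, would also move the 555 genes outside the interferon lists that moved the same way in untreated and DMSO cultures, but turned to that direction their median between the libraries labelled PBS was -0.00896 (quartiles -0.0581 and 0.0492), against 0.60 and 0.40 in those cultures. If the groups labelled sgScramble IFNγ and sgArid1a PBS carried each other's labels, the labelled treatment contrast under sgScramble would be the knockout contrast. Across genes outside the interferon lists it correlated at 0.35 with the untreated knockout contrast, against 0.0024 for the PBS labels. Across all genes these were 0.351 and 0.103. But the median of the 555 genes was 0.18 (quartiles 0.0254 and 0.44), under 0.5 times 0.40. That exchange therefore cannot be told apart from an effect of the treatment or other exchanges, which were not tested. The interaction would be the same under that exchange, because the exchanged groups enter it with the same sign.

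In the libraries labelled as double knockouts, reads of near-identical copies may have been aligned or counted differently. Of genes with over 50% shared 31-mers 31.9% fell below -1, while of abundant genes with at most 5% shared 0.203% did, which speaks against a general loss of abundant transcripts. A role of Cgas that Sting1 lacks would not reach both sets of libraries, and 33.1% of the genes with over 50% shared fell with the Sting1 label. An effect of the pathway that both genes serve changes together with the set of libraries, so the design cannot separate it. Such an effect would have to follow shared sequence. Among abundant genes with over 50% shared 31.5% fell below -1 with the Cgas label, against 0.203% with at most 5%, which argues against it for these genes.

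In tumors labelled sgArid1a, muscle genes and immune markers rose together. Their muscle median of 2.55 restates the pattern, and with only 2 muscle markers measured in untreated culture, skeletal muscle in the samples cannot be told apart from muscle genes expressed by tumor cells. A lower share of melanoma cells as the whole change would raise markers of all other cells, but the erythroid median was -1.12. Whether more macrophages account for the whole interferon rise cannot be told apart from a rise within cells, since the interferon median of 0.87 lies between the macrophage quartiles of 0.73 and 1.26.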

How the results depend on the processing

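Median centring, quantile normalization, restriction to genes with little shared sequence, the set without the IFNγ experiment and loci summed per subfamily were chosen after the results had been seen. The type I interferon list kept its direction and its call at the preset correlation in 144 of 144 alternatives over 16 comparisons. With an estimated correlation it was called in 9 of the 16 and not in 7: tumors, BD98, MC38 cells, MEFs, the Sting1 label and the labelled IFNγ treatment under either guide label. That test has little power with the few libraries of tumors, MC38 cells and MEFs, so the lack of a call there does not count against the list. Among genes with at most 5% shared 31-mers it was called at the preset correlation alone for both double-knockout labels. For single named genes, 2836 of 2998 alternatives kept direction and call (1638 above 0 and 1198 below), 147 lost the call (89 above and 58 below), 15 gained it (13 above and 2 below) and 0 turned. Counts of changed genes stayed within 1.5 times the reported count in 97 alternatives and moved further in 49. Leaving out a library left 1 in its group, which is assumed to vary like the other groups; counts ranged from 208 to 241 for the PBS labels, 488 to 1597 for the IFNγ labels, 57 to 881 for the interaction, 451 to 2840 in untreated cultures, 1468 to 2130 for the Cgas label, 1610 to 3072 for the Sting1 label (1893 to 2101 where a sgArid1a library was left out), 0 to 1 for anti-IFNAR, 182 to 3240 with DMSO, 4 to 18 with ruxolitinib, 86 to 810 for anti-IFNAR after BD98 and 1156 to 2274 in MC38 cells. Without the filter, which adds genes, the count was 56 for the interaction, 343 for anti-IFNAR after BD98 and 1482 in MC38 cells. With only the libraries compared it was 642 in untreated cultures, 5135 for the Cgas label, 18 for anti-IFNAR and 89 with ruxolitinib. With at most 5% shared 31-mers fewer genes are tested, and it was 1737 and 2078 for the Cgas and Sting1 labels. Repeats had 571 calls per locus and 6 with loci summed per subfamily, against 0. The set raised in either of the other experiments returned with medians of -0.0052 (Cgas label) and -7.4e-05 (anti-IFNAR), no longer called at the preset correlation, and 0.0114 (Sting1 label), turned in sign. With an estimated correlation camera still called it lower for anti-IFNAR (p = 0.025). Without the IFNγ experiment the medians turned to 0.0743 (Cgas label), 0.0846 (Sting1 label), 0.0213 (anti-IFNAR) and 0.00865 (anti-IFNAR after BD98), though in the last 35 of 251 fell, 0 rose and camera called the set lower. The cause of these moves was not tested. Replicate numbers mark no shared animal or batch in the labels, and deviations of same-numbered libraries correlated at -0.510 in tumors, 0.686 in MEFs, 0.0837 in MC38 cells, -0.381 in untreated and -0.0696 in DMSO cultures. With a replicate block the count moved to 678 in untreated cultures, 355 for anti-IFNAR after BD98 and 5013 in MEFs. It was 6308 in tumors, 353, 4343, 5271, 890 and 122 in the IFNγ experiment, 2454 for the Cgas label, 3 for anti-IFNAR, 737 with DMSO, 20 with ruxolitinib, 6723 with BD98, 2806 in MC38 cells and 0 for repeats, and the return set kept its direction and call in 5 of 5 comparisons with the block. No paired analysis was possible because the columns of the Sting1 double knockout carry no number, for that group alone. DESeq2, RLE size factors and another pseudocount were not run on the log2 tables, which hold no counts. The depth of 8.7 M reads in 1 untreated sgScramble library limits the precision of weakly expressed genes there, and this was not tested.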

Other observations

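No test in this part was chosen after its result had been seen. In melanoma cultures with the sgArid1a guide, Trpm1 fell by 2.27 ± 0.10 (adjusted p = 2.5e-08) in untreated and fell by 1.52 ± 0.10 (adjusted p = 1.7e-06) in DMSO cultures, and in the IFNγ experiment, whose labels Arid1a does not bear out, it was at 0.13 ± 0.04 (adjusted p = 0.070) between the guides labelled PBS and at -2.21 ± 0.04 between the treatments labelled sgScramble. Of 17 pigment genes 8 fell in untreated and 5 in DMSO cultures (adjusted p = 0.094 and adjusted p = 0.25 with an estimated correlation). Trib3 was at -2.77 and -2.35 and Ddit3 at -2.32 and -1.36 in untreated and DMSO cultures, where 12 of 17 stress response genes fell and 4 rose in each (adjusted p = 0.036 and adjusted p = 0.17 with an estimated correlation). The sterol gene Hmgcs1 rose by 0.69 and 0.61.

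Across genes, the fold changes of MC38 cells and MEFs correlated with r = 0.407, where genes are not independent replicates. Both raised 168 genes against 31.1 expected and lowered 212 against 64.6 expected. Tumors and untreated cultures correlated with r = 0.0221, and both raised 249 genes against 142.5 expected and lowered 255 against 218.8 expected. Own fold changes correlated with those of the authors' deposited tables at 0.652 in MC38 cells and at 0.935 in untreated cultures.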
